A study of Homo sapiens with 32 samples.

How the data were processed

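RNA was measured in 32 libraries of engineered tissues of HUtSMC, commercial human uterine smooth muscle cells, in 4 groups of 8 made from 2 gel stiffnesses (13 and 90 kPa) and 2 fibronectin patterns (aligned lanes and isotropic). Per the labels, total RNA was taken with Trizol, purified with a miRNeasy micro kit, and cleaned on a Zymo column. Non-directional libraries were made with the NEBNext Ultra II kit, and paired-end reads of 150 bases came from a NovaSeq 6000. The reads of such libraries do not tell the strand, so overlapping genes on opposite strands cannot be fully separated. The donor, lot and passage of the cells and the meaning of the library numbers 1 to 8 are not given in the sources used here. The deposited table's own name refers to more than 1 sequencing run, but the run of each library is not given.

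The deposited table holds expected counts, that is, reads per gene as estimated by the expectation-maximization counter of Partek after alignment with STAR to hg38, not scaled to depth. Versions and the annotation release are not given in the sources used here. The table has 24095 genes, each with at least 10 counts over all libraries, and 23.2% of its values were not whole within 0.01, so values were rounded. Gene names and positions come from the table and the annotation supplied with it, and 24052 genes were matched to a name.

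Total counts ran from 17.01 to 35.24 M per library. A count of 0 allows up to 3 counts. This limit covers counting error only and takes no account of PCR copies, which are not independent molecules. Intervals of fold changes come from the edgeR fit described below and also include spread between libraries. Genes were filtered with filterByExpr on the group, which left 15417 genes with 99.92% of the counts. Log2 CPM used a prior count of 2 and TMM factors.

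Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM, robust quasi-likelihood F-test, two-sided, without a term other than the group), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 8 comparisons were 90 kPa isotropic minus 13 kPa aligned (combined), the average effects of stiffness and of pattern, each factor within each level of the other, and the interaction. Estimates are log2 fold changes with standard errors from the same fit. Gene lists numbered 35, fixed before the data were examined, and the 33 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The immune and adipocyte marker lists had fewer members tested and were not analysed. Camera with an estimated correlation and fry were run beside it, and fry called 0 lists in the 3 main comparisons, with smallest adjusted p of 0.715, 0.880 and 0.818. Library measures were compared with exact permutation tests.

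The genes named in each main comparison were to be the 8 largest changes in each direction among called protein-coding genes, of which there were none, up to 3 members of each list with the smallest adjusted p, and 10 genes always given. Not all members that this rule allows are named. Genes outside it are marked where they appear.

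Alternatives chosen before the data were examined were the size factors and the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no filter, a stricter filter of at least 5 CPM in at least 8 libraries, a fit without robust estimation, a fit on the compared groups alone, a replicate block by library number, and the estimated correlation. The Wald test was run with the default settings of DESeq2, which can replace outlying counts in groups of this size. After the libraries were seen to fall into sets, further alternatives were added. These were a term for the 4 sets found by Ward clustering of log2 CPM, a term for 5 sets, 3 surrogate variables from sva 3.50.0, fits within or without single sets, a fit without the deepest library, and permutations of the labels within sets (100000 permutations), for the average pattern also without the 3-library set. The edgeR biological coefficient of variation was 28.3% without and 9.17% with the set term.

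The fit was tested on simulated data with 15417 genes at the depth and spread of these libraries. For the average stiffness comparison, 50 genes per fold were changed. The collagen list was also moved up 1.25-fold and was not counted among the unchanged genes. Without a set term it called 26% of genes changed 1.25-fold, 62% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, and 0 of 15197 unchanged genes. With the set term the shares were 62%, 76%, 92% and 100%, with 5 unchanged genes called. The sets were built into the simulated values and given to that fit as known. In the data they were drawn from the same values, so these shares do not show how the set term behaves there. Camera at the preset correlation called 1 of the 32 other lists without the set term and 0 with it. Apart from the sets, the simulated genes varied independently of each other, unlike genes of a list in the data. These counts therefore do not show how often camera calls lists falsely in the data. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for permutation tests and plots.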

Results

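RNA was sequenced from engineered tissues of HUtSMC, commercially supplied smooth muscle cells of the human uterus. The tissues grew on gels of 13 or 90 kPa that carried fibronectin either as lanes, called aligned here, or as an isotropic pattern. Each of the 4 combinations had 8 libraries, numbered 1 to 8. In the study's design, 13 kPa aligned tissue stands for healthy and 90 kPa isotropic tissue for fibrotic myometrium, the muscle wall of the uterus. Total counts per library ran from 17.01 to 35.24 M, with a median of 20.4 M. The group means were 21.1 ± 2.61 M for 13 kPa aligned, 20.04 ± 1.53 M for 13 kPa isotropic, 22.6 ± 5.51 M for 90 kPa aligned and 19.6 ± 1.67 M for 90 kPa isotropic (SD, n = 8 each). In 20 exact permutation tests of depth, detected genes, the share of the 20 highest genes and the share of mitochondrially encoded genes, the smallest adjusted p was 0.631. It belonged to the mitochondrial share, 3.05% ± 0.109 in 90 kPa isotropic and 2.88% ± 0.161 in 13 kPa isotropic libraries (SD, n = 8, two-sided exact p = 0.0315).

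Genes of type I collagen and fibronectin were expressed at very high levels, and those of smooth muscle and of uterine signals at levels that ran down to too low to test. COL1A1, the main chain of type I collagen (ENSG00000108821.14, hg38 chromosome 17, 50184101 to 50201632), had 26030 ± 8076 counts per M (CPM) in 13 kPa aligned and 21150 ± 4732 CPM in 90 kPa isotropic tissues (SD, n = 8 each). FN1, the gene of fibronectin, had 28920 ± 12040 CPM and 23260 ± 7629 CPM in the same groups. OXTR, the receptor for the labor hormone oxytocin (ENSG00000180914.11, chromosome 3, 8750381 to 8769628), had 96.2 ± 71.0 CPM in 13 kPa aligned and 76.9 ± 13.2 CPM in 90 kPa isotropic tissues. GJA1, the gap junction gene that couples myometrial cells, had 441 ± 58.4 CPM and 419 ± 51.2 CPM. ESR1 and PGR, the estrogen and progesterone receptor genes, were low, with 2.47 ± 0.653 CPM and 13.4 ± 2.87 CPM in 13 kPa aligned tissues (SD, n = 8). MYH11, the smooth muscle myosin heavy chain, had 228 counts over all 32 libraries together and was too low to test.

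The largest differences in the data separated libraries within the groups. Clustering of log2 CPM, done after the values were seen, placed the 32 libraries in sets of 16, 7, 6 and 3, and the 16-library set held numbers 5 to 8 of every group. These 4 sets took up 58.2% of the variance between libraries, a share that is high by construction, because the clustering drew them from the same values. The 4 groups took up 5.65%, against 9.68% that chance gives for 4 classes of libraries. The 3-library set, made of 1 library each of 13 kPa aligned, 13 kPa isotropic and 90 kPa aligned, had the highest median expression of the contractile, collagen, matrix glycoprotein and cytokine lists, though not of matrix remodelling enzymes, and the 90 kPa isotropic group had no library in it. ACTA2, smooth muscle actin (ENSG00000107796.13, chromosome 10, 88935074 to 88991339), had a median of 3302 CPM there (range 2991 to 3414), against medians of 226, 527 and 184 CPM in the sets of 16, 6 and 7. DES, the gene of the muscle filament desmin, had a median of 48.3 CPM against 1.78, 1.19 and 1.44 CPM, and CNN1, the gene of calponin, 179 CPM against 16.1, 15.3 and 16.3 CPM. OXTR had a median of 269 CPM against 81.0, 66.0 and 67.7 CPM, FN1 51770 CPM against 21100, 35960 and 15910 CPM, and the chemokine gene CXCL8 337 CPM against 40.0, 57.2 and 27.1 CPM. TGFB1, a growth factor of fibrosis, was lowest there, with 112 CPM against 308, 224 and 223 CPM. MKI67, a marker of dividing cells chosen after its values were seen, had a median of 8.86 CPM in the 3-library set, 36.3 CPM in the 6-library set, 124 CPM in the 16-library set and 202 CPM in the 7-library set. The labels give no reason for the sets, so the main comparisons below are also given, for most of the genes named with large estimates, with a term for them.

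**Figure D1:**
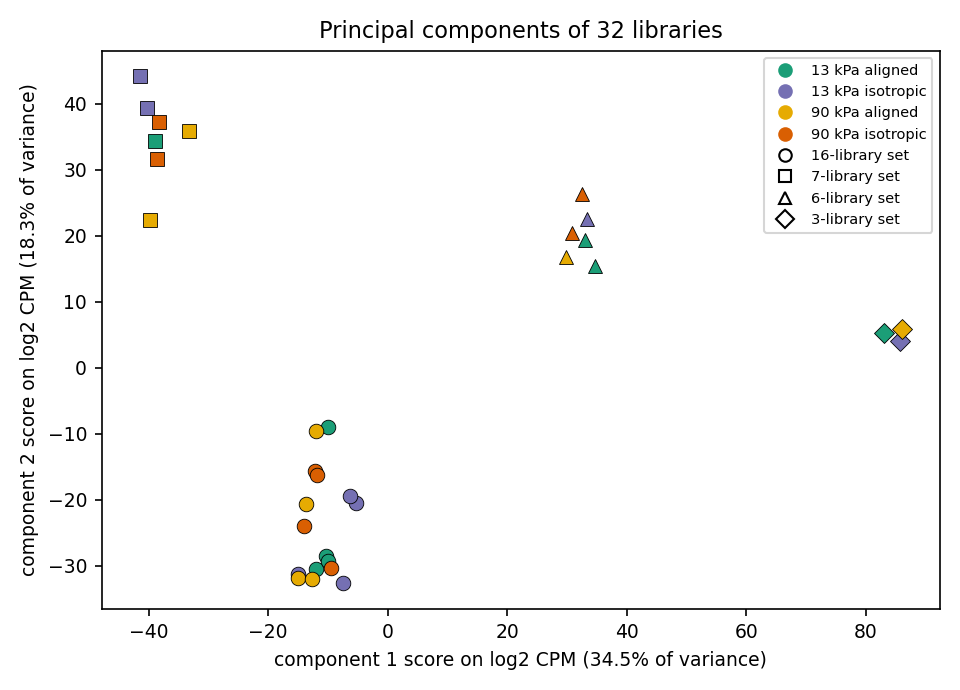
Principal components 1 and 2 of log2 CPM of the genes tested, with their shares of the variance, 34.5% and 18.3%, on the axes and 1 point per library. Colors and symbols mark the 4 groups and the 4 sets, and libraries lie with their set, not with their group.

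The combined comparison asked how tissues on the fibrotic-like substrate, 90 kPa isotropic, differ from those on the healthy-like one, 13 kPa aligned. Most contractile, collagen, matrix glycoprotein and cytokine genes had lower estimates, and cell cycle genes higher ones, in 90 kPa isotropic tissues. No single gene passed: of 15417 genes, 0 were called by edgeR (every adjusted p = 1), with 168 at an unadjusted p under 0.05 against 771 that chance gives, and 0 by DESeq2 (193 unadjusted) and 0 by limma voom (1546 unadjusted). The edgeR fit without a set term counts differences between the sets as spread within groups, which can lower the count of 168. With the set term 641 genes were at an unadjusted p under 0.05 by edgeR. In each list below, 0 members passed over all genes and 0 when adjusted over the list alone.

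Of the 23 tested contractile genes, 21 had estimates below 0, and the list ranked lower than other genes (camera adjusted p = 0.000701; adjusted p = 0.537 with an estimated correlation). The log2 fold change was -2.0 ± 0.998 for DES (SE, n = 8 per group), -1.20 ± 0.726 for ACTA2, -1.14 ± 0.652 for CNN1 and -0.97 ± 0.563 for LMOD1, an actin nucleator of smooth muscle. These 4 estimates with the set term were 0.11 ± 0.153, -0.06 ± 0.0514, 0.00 ± 0.0737 and -0.04 ± 0.0629. Among the contraction-associated genes, 11 of 16 had estimates below 0 (camera adjusted p = 0.358). OXTR was at -0.32 ± 0.325 and, with the set term, at 0.10 ± 0.0607, while GJA1 was at -0.07 ± 0.104 and 0.01 ± 0.0362. PTGS2, the inducible enzyme of prostaglandin synthesis, was at -0.44 ± 0.258, the prostaglandin E synthase gene PTGES at -0.76 ± 0.615, and RGS2, a brake on G protein signals, at -0.19 ± 0.145. PTGES was at 0.08 ± 0.254 with the set term.

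All 20 tested collagens had estimates below 0 (camera adjusted p = 0.000238; adjusted p = 0.537 with an estimated correlation), as did 31 of 33 matrix glycoproteins and proteoglycans (camera adjusted p = 9.39e-06; adjusted p = 0.537 with an estimated correlation). The log2 fold change was -0.30 ± 0.213 for COL1A1, -0.92 ± 0.556 for COL14A1, -0.85 ± 0.592 for COL11A1, -0.31 ± 0.267 for FN1, -1.29 ± 0.701 for the small proteoglycan gene FMOD and -0.61 ± 0.432 for ASPN. ELN, the gene of elastin, was at -2.13 ± 0.975 with only 461 counts over all libraries. With the set term COL1A1 was at -0.10 ± 0.0520, COL14A1 at -0.31 ± 0.162, COL11A1 at 0.05 ± 0.0948, FN1 at -0.07 ± 0.0395, FMOD at -0.12 ± 0.173, ASPN at -0.49 ± 0.354 and ELN at -0.39 ± 0.503.

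Of 22 cytokine and NF-kB genes, 21 had estimates below 0 (camera adjusted p = 0.000238; adjusted p = 0.537 with an estimated correlation). The neutrophil-attracting chemokine genes CXCL2, CXCL6 and CXCL8 were at -2.23 ± 0.998, -1.97 ± 0.889 and -1.11 ± 0.532, and at -0.09 ± 0.317, -0.43 ± 0.158 and -0.27 ± 0.106 with the set term. In the TGF-beta list, 15 of 19 estimates were below 0 (camera adjusted p = 0.00375; adjusted p = 0.537 with an estimated correlation). SMAD7, an inhibitor of TGF-beta signaling, was at -0.18 ± 0.0826 and at -0.16 ± 0.0722 with the set term, BAMBI at -0.59 ± 0.382 and at -0.08 ± 0.107 with the set term, ID3 at -0.31 ± 0.210 and TGFB1 itself at 0.00 ± 0.211. CCN2, the gene of connective tissue growth factor, was at -0.20 ± 0.186, and its YAP/TAZ target list had a camera adjusted p of 0.0557 with 18 of 24 estimates below 0. The ribosomal protein list ranked lower with small differences (35 of 36 below 0, median log2 fold change -0.09, camera adjusted p = 1.54e-05; adjusted p = 0.537 with an estimated correlation), with RPS19 at -0.23 ± 0.162 and RPL5 at -0.12 ± 0.0861. NR4A3, an immediate early gene with 942 counts in all, was at -1.69 ± 0.685, at -0.24 ± 0.316 with the set term and at 0.351 with limma voom.

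All 34 cell cycle genes had estimates above 0 (median 0.35, camera adjusted p = 1.26e-06; adjusted p = 0.537 with an estimated correlation). KIF23, needed for the last step of cell division, was at 0.38 ± 0.371, the replication helicase gene MCM6 at 0.22 ± 0.212 and PCNA at 0.15 ± 0.167. In the fit with the set term they were at 0.11 ± 0.0564, 0.04 ± 0.0497 and 0.03 ± 0.0485. Interferon response genes ranked higher, with 14 of 22 above 0 (camera adjusted p = 0.0247; adjusted p = 0.537 with an estimated correlation). Both MX1, at 1.03 ± 0.481, and IFIT1, at 0.66 ± 0.313, encode antiviral proteins, and with the set term they were at 0.67 ± 0.426 and 0.59 ± 0.233. Cholesterol synthesis genes also ranked higher, with 21 of 24 above 0 (camera adjusted p = 0.0406; adjusted p = 0.600 with an estimated correlation), with MVK at 0.21 ± 0.169 and FDFT1 at 0.17 ± 0.143. ESR1 was at 0.05 ± 0.167 and PGR at 0.00 ± 0.125. The marker lists of fibroblasts, pericytes, endothelium, epithelium, decidual stroma, bone and cartilage, and nerve were not called, with camera adjusted p from 0.169 to 0.978. The mean and the median differed in sign for the epithelial and the bone and cartilage markers, and the endothelial list ranked upward with both below 0.

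In the same list test with the set term, 7 lists were called at the preset correlation. Collagens (camera adjusted p = 0.00179), matrix glycoproteins (0.00887), matrix remodelling enzymes (0.00279), TGF-beta (0.00279) and immediate early genes (0.00131) ranked lower, and interferon (7.62e-05) and cholesterol synthesis genes (0.00684) higher (smallest adjusted p = 0.384 with the set term and an estimated correlation). Contractile (0.388), cell cycle (0.0765), cytokine (0.0768) and ribosomal genes (0.151) were not called with it, and permutation within the sets called 0 of 33 lists (smallest adjusted p = 0.446). The interferon list differed by 0.169 with set means removed (permutation p = 0.0740, adjusted p = 0.529), but by -0.0185 (permutation p = 0.569) in the 16-library set. With 5 sets, however, the 16-library set parted unevenly between these groups. Numbers 6, 7 and 8 of 13 kPa aligned fell together, apart from number 5. Number 8 of 90 kPa isotropic fell with the former, and numbers 5, 6 and 7 with the latter. Values with the set term, with set means removed or within the 16-library set can therefore still hold differences between these parts.

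Without the 3-library set, edgeR called 0 genes (148 at an unadjusted p under 0.05), and within the 16-library set it called 0 (444 unadjusted). In the 7-library and 6-library sets, with 7 and 6 libraries over 4 groups, it called 5 and 10 genes. The 95% interval of the fold change lay within 2-fold for 84.2% of genes, and for 92.5% with the set term.

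**Figure D2:**
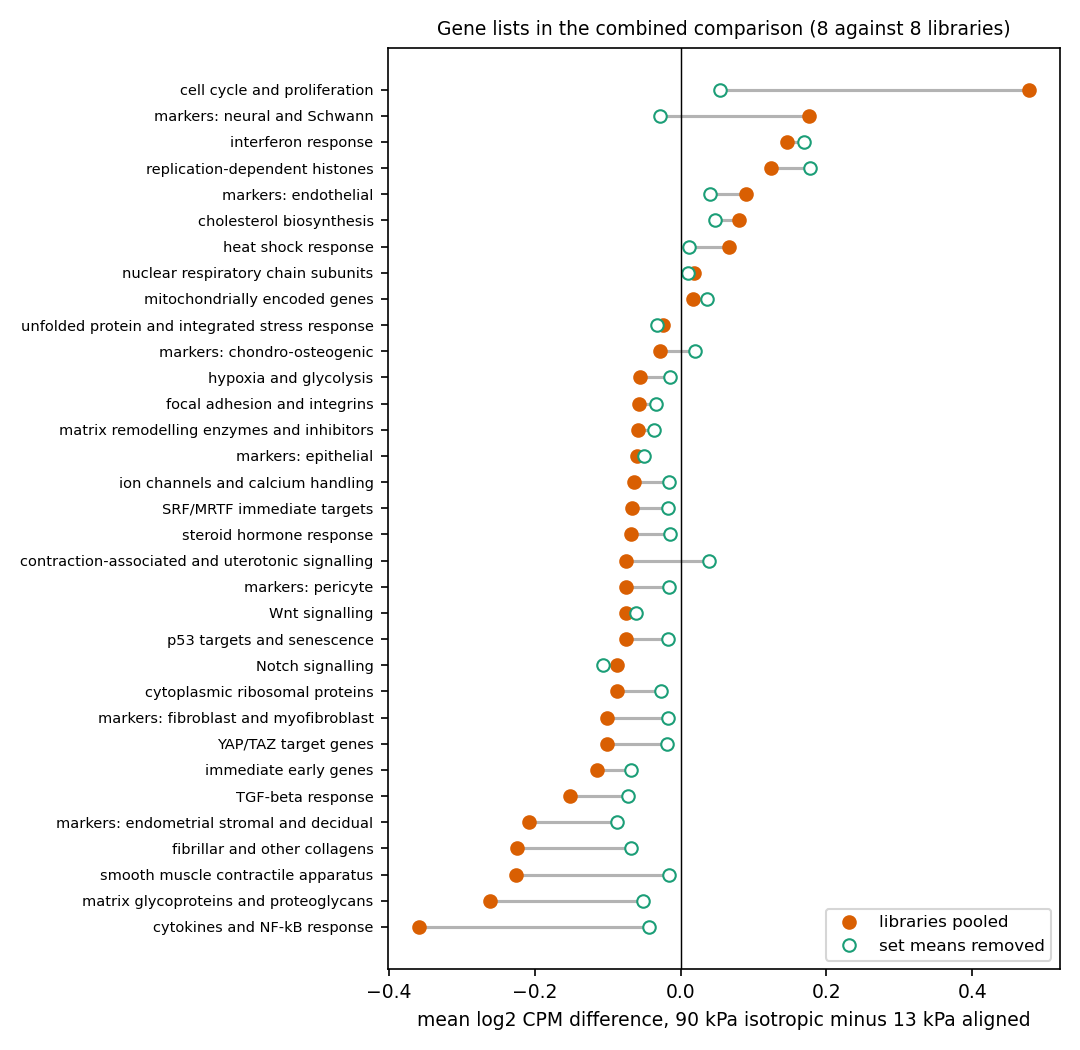
Mean log2 difference of each gene list between 90 kPa isotropic and 13 kPa aligned tissues, from all libraries and with the mean of each set removed. The cell cycle list lies at 0.48 from all libraries and at 0.05 with set means removed, and the collagen list at -0.22 and -0.07.

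The average stiffness comparison asked what 90 kPa against 13 kPa does across both patterns. On the stiffer gels most contractile and matrix estimates lay below 0 and cell cycle estimates above 0, each within the spread of the libraries. ACTA2 was at -0.60 ± 0.508 (SE, n = 16 per stiffness), COL1A1 at -0.17 ± 0.151, FN1 at -0.17 ± 0.189 and CCN2 at -0.09 ± 0.131, and with the set term they were at 0.00 ± 0.0361, -0.05 ± 0.0366, -0.03 ± 0.0278 and -0.02 ± 0.0314. By edgeR 0 genes were called (every adjusted p = 1, 126 unadjusted), by DESeq2 0 (159 unadjusted) and by limma voom 0 (1087 unadjusted), and 0 members of any list were called over all genes or when adjusted over the list alone.

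The contractile list ranked lower at 90 kPa (21 of 23 below 0, camera adjusted p = 0.0211; adjusted p = 0.783 with an estimated correlation), with DES at -1.02 ± 0.677 and LMOD1 at -0.51 ± 0.394, which were at -0.04 ± 0.102 and -0.07 ± 0.0438 with the set term. Matrix glycoproteins ranked lower too (31 of 33 below 0, camera adjusted p = 0.000650; adjusted p = 0.783 with an estimated correlation), with FMOD at -0.77 ± 0.487 and ELN at -0.96 ± 0.658. Both shrank with the set term, to -0.04 ± 0.121 and -0.06 ± 0.339, and FMOD was at 0.00152 with surrogate variables and ELN at 0.409 with limma voom. Collagens did not pass (18 of 20 below 0, camera adjusted p = 0.0584), with COL14A1 at -0.55 ± 0.389 and COL1A2 at -0.21 ± 0.198, and at -0.16 ± 0.113 and -0.06 ± 0.0362 with the set term. Ribosomal proteins ranked lower (30 of 36 below 0, camera adjusted p = 0.00852; adjusted p = 0.783 with an estimated correlation). All 34 cell cycle genes lay above 0 (camera adjusted p = 7.20e-05; adjusted p = 0.783 with an estimated correlation), with KIF23 at 0.21 ± 0.262, MCM6 at 0.14 ± 0.150 and UBE2C, a mitotic ubiquitin enzyme, at 0.28 ± 0.391. These 3 were, with the set term, at 0.09 ± 0.0395, 0.05 ± 0.0348 and 0.14 ± 0.0584. The list test with the set term called the cell cycle (camera adjusted p = 0.000418) and histone lists (0.0308) as higher and matrix glycoproteins (0.0308) as lower, but neither contractile (0.424) nor ribosomal genes (0.578). The smallest adjusted p was 0.287 with the set term and an estimated correlation, and permutation within the sets called 0 of 33 lists (smallest adjusted p = 0.200).

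Among contraction-associated genes, 12 of 16 estimates were below 0 (camera adjusted p = 0.636). OXTR was at -0.16 ± 0.229 and, with the set term, 0.04 ± 0.0424, GJA1 at -0.06 ± 0.0736, the prostaglandin F receptor gene PTGFR at -0.26 ± 0.161 and RGS2 at -0.11 ± 0.103. AVPR1A, a vasopressin receptor with 347 counts in all, was at 0.47 ± 0.207. Histone genes had 7 of 8 estimates above 0 (camera adjusted p = 0.0843). H4C14 was at 0.76 ± 0.366 and H2BC4 at 0.43 ± 0.277, and both have near-identical copies among which reads can be shared. The YAP/TAZ targets, often used as a readout of matrix stiffness, had 17 of 24 estimates below 0 (camera adjusted p = 0.259), with NUAK2 at -0.20 ± 0.185. TGFB1 was at 0.01 ± 0.149, ESR1 at -0.06 ± 0.118 and PGR at -0.02 ± 0.0883. The 95% interval lay within 2-fold for 94.7% of genes, and for 97.6% with the set term.

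The average pattern comparison asked what an isotropic against an aligned layout does across both stiffnesses. Most immediate early, cytokine, collagen and contractile estimates lay below 0 on the isotropic pattern, and most cholesterol synthesis estimates above 0. No gene passed: edgeR called 0 (every adjusted p = 1, 136 unadjusted), DESeq2 0 (162 unadjusted) and limma voom 0 (905 unadjusted), with 0 list members called over all genes or when adjusted over the list alone.

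Of 23 immediate early genes, the first to respond to growth factors and stretch, 20 had estimates below 0 (camera adjusted p = 0.00842; adjusted p = 0.434 with an estimated correlation). NR4A3 was at -1.21 ± 0.481 and IER3 at -0.17 ± 0.114 (SE, n = 16 per pattern). NR4A3 had 14.6 CPM in 13 kPa aligned number 3 against 0.402 to 2.14 CPM in the other libraries of that group, and its estimate was -0.21 ± 0.227 with the set term, 0.08 with DESeq2 and 0.26 with limma voom. IER3 was at -0.09 ± 0.0367 with the set term. With set means removed the mean of this list was -0.09, and its isotropic minus aligned difference was -0.01 within the 16-library set, -0.14 within the 7-library set, -0.07 within the 6-library set and -0.453 within the 3-library set, which has 1 isotropic library. Without the 3-library set the mean with set means removed was -0.0558 (permutation p = 0.0704). Cytokine genes ranked lower (21 of 22 below 0, camera adjusted p = 0.000543; adjusted p = 0.595 with an estimated correlation), with CXCL2 at -1.62 ± 0.686, CXCL3 at -0.74 ± 0.334 and CXCL8 at -0.80 ± 0.374. In the fit with the set term these were at -0.37 ± 0.224, -0.39 ± 0.181 and -0.24 ± 0.0747. The cytokine list differed by -0.0668 with set means removed (permutation p = 0.0749, adjusted p = 0.310), by -0.0142 (permutation p = 0.559) in the 16-library set, by -0.479 in the 3-library set with its 1 isotropic library, and by -0.0280 (permutation p = 0.264) with set means removed and without the 3-library set. The sequences of CXCL2 and CXCL3 are similar, so reads can be shared between them.

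All 20 collagens lay below 0 on the isotropic pattern (camera adjusted p = 0.000928; adjusted p = 0.595 with an estimated correlation), with COL1A1 at -0.13 ± 0.151, COL4A2 at -0.13 ± 0.121 and COL11A1 at -0.50 ± 0.416. Matrix glycoproteins had 30 of 33 below 0 (camera adjusted p = 0.00124; adjusted p = 0.595 with an estimated correlation), with FN1 at -0.15 ± 0.189, ELN at -1.17 ± 0.658 and the matrix gene TNC at -0.18 ± 0.143. Contractile genes had 22 of 23 below 0 (camera adjusted p = 0.0103; adjusted p = 0.595 with an estimated correlation), with ACTA2 at -0.60 ± 0.508, DES at -0.98 ± 0.677, CNN1 at -0.55 ± 0.455 and TAGLN at -0.27 ± 0.228. With the set term ACTA2 was at -0.06 ± 0.0360, DES at 0.16 ± 0.103, CNN1 at 0.02 ± 0.0510, TAGLN at -0.09 ± 0.0330, COL1A1 at -0.05 ± 0.0364, COL11A1 at -0.05 ± 0.0661 and ELN at -0.33 ± 0.342. All 36 ribosomal proteins lay below 0 with a median of -0.05 (camera adjusted p = 0.000543; adjusted p = 0.595 with an estimated correlation).

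The TGF-beta list had 16 of 19 below 0 (camera adjusted p = 0.0103; adjusted p = 0.595 with an estimated correlation), with SMAD7 at -0.15 ± 0.0584, and at -0.14 ± 0.0505 with the set term, and TGFB1 at 0.00 ± 0.149. Notch signaling had 13 of 15 below 0 (camera adjusted p = 0.0173; adjusted p = 0.289 with an estimated correlation), with the ligand gene JAG2 at -0.31 ± 0.312 and the feedback gene NRARP at -0.27 ± 0.271, both with few counts. Cell cycle genes were all above 0 (34 of 34, camera adjusted p = 0.000928; adjusted p = 0.630 with an estimated correlation), but with the set term their median was -0.01. Cholesterol synthesis genes had 20 of 24 above 0 (camera adjusted p = 0.00378; adjusted p = 0.595 with an estimated correlation), with HSD17B7 at 0.25 ± 0.177 and FDFT1 at 0.13 ± 0.101. Interferon genes had 14 of 22 above 0 (camera adjusted p = 0.0263; adjusted p = 0.595 with an estimated correlation), with MX1 at 0.70 ± 0.338, IFI44L at 0.84 ± 0.441 and IFIT1 at 0.39 ± 0.221. These 3 were at 0.47 ± 0.291, 0.86 ± 0.388 and 0.36 ± 0.161 with the set term, and with limma voom MX1 was at -0.0689. MX1 reached 15.93 CPM in 1 library of the 7-library set, whose median was 3.316 CPM. The interferon list differed by 0.113 with set means removed (permutation p = 0.0846, adjusted p = 0.310) and by 0.0189 (permutation p = 0.766) in the 16-library set.

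The list test with the set term called 8 lists for the pattern. Immediate early (camera adjusted p = 2.84e-06), collagen (0.000471), matrix remodelling (0.00256), unfolded protein and stress response (0.00530), Notch (0.0170) and TGF-beta genes (0.0198) ranked lower, and cholesterol synthesis (5.34e-06) and interferon genes (0.000610) higher (smallest adjusted p = 0.298 with the set term and an estimated correlation). Permutation within the sets called 0 of 33 lists (smallest adjusted p = 0.107), and collagens differed by -0.0526 (permutation p = 0.115) in it and by -0.0148 (permutation p = 0.774) in the 16-library set.

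Of 16 contraction-associated genes, 10 had estimates below 0 for the pattern (camera adjusted p = 0.415). With or without the set term, 0 passed over all genes, and with it 1, PTGFR, passed when adjusted over the list alone. OXTR was at -0.16 ± 0.229 and 0.06 ± 0.0425 with the set term, GJA1 at -0.02 ± 0.0736, AVPR1A at -0.34 ± 0.206 and PTGS2 at -0.28 ± 0.182. Outside this list, CCN2 was at -0.11 ± 0.131, ESR1 at 0.12 ± 0.118 and PGR at 0.01 ± 0.0883. The 95% interval lay within 2-fold for 94.9% of genes, and for 97.9% with the set term.

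**Figure D3:**
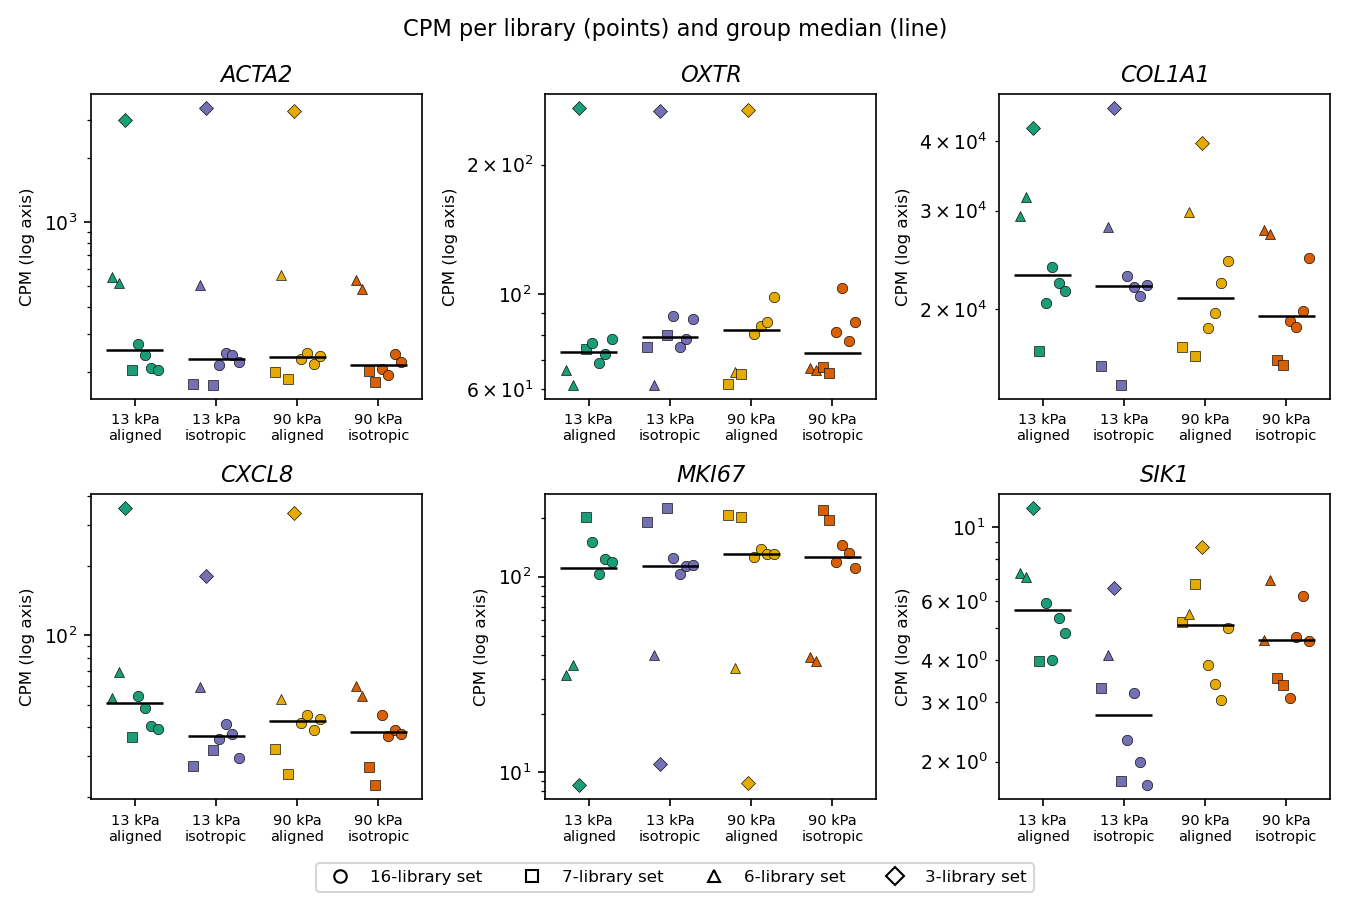
CPM of genes named in the text in each of the 32 libraries, on a log axis, by group, with symbols for the 4 sets. The libraries of the 3-library set stand apart within their groups, as for ACTA2 with 2991 to 3414 CPM.

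The 4 single-factor comparisons asked for the effect of one property with the other held fixed, and the interaction asked whether the effect of stiffness differs between patterns. By edgeR 0 genes passed for stiffness in aligned tissues (101 unadjusted), stiffness in isotropic tissues (136), pattern at 13 kPa (98), pattern at 90 kPa (131) and the interaction (110), with every adjusted p at 1. DESeq2 also called 0 (124, 150, 119, 155 and 130 unadjusted), and limma voom called 0 except for 2 genes in the pattern at 13 kPa. Those 2 genes were SIK1 and CEBPB-AS1, an RNA antisense to CEBPB that an unstranded library cannot separate from its overlap.

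SIK1, a kinase induced by cAMP signals (ENSG00000142178.9, hg38 chromosome 21, 43414483 to 43427131), was lower on isotropic than on aligned gels at 13 kPa. It had 3.12 ± 1.64 CPM in 13 kPa isotropic and 6.23 ± 2.42 CPM in 13 kPa aligned tissues, and 4.63 ± 1.36 CPM and 5.19 ± 1.87 CPM in the 90 kPa isotropic and aligned tissues (SD, n = 8 each). It was named after its values were seen. Its log2 fold change at 13 kPa was -0.99 ± 0.266 (edgeR adjusted p = 1), and it fell by 0.96 ± 0.164 with the set term (edgeR adjusted p = 0.0113), where it was the 1 gene called. At 13 kPa the isotropic minus aligned difference of log2 CPM was -1.12 in the 16-library set (4 isotropic and 4 aligned libraries), -0.70 in the 7-library set (2 and 1), -0.78 in the 6-library set (1 and 2) and -0.78 in the 3-library set (1 and 1), so only the first rests on replicates on both sides. With set means removed the difference was -0.943 for the pattern at 13 kPa (two-sided exact permutation p = 0.000794), -0.0625 for the pattern at 90 kPa (p = 0.754), 0.75 for stiffness in isotropic tissues (p = 0.00714), -0.223 for stiffness in aligned tissues (p = 0.167) and -0.205 for the combined comparison (p = 0.185), none adjusted for the choice of this gene. The interaction was 0.83 ± 0.373 (edgeR adjusted p = 1), so an effect of stiffness on the pattern difference of SIK1 did not pass. A near-identical copy, SIK1B, has no entry of its own in the table, so reads of both may be counted as SIK1.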

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

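The test of set sizes against exchanged labels, the tests of set shares and gene correlation for the combined comparison, the counts of genes over other splits, and every within-set value were chosen only after the result was seen, as was the separation of collagens and matrix glycoproteins from the other lists of the combined comparison and the demand that the set-centred difference of immediate early genes also hold without the 3-library set. In each group of 8 libraries, a library was singled out when its gap to the nearest other library exceeded the share of the group's range that Dixon's 95% critical value allows. For genes the gap and range were taken on log2 CPM, while the values below are given as CPM. The values tested were mostly of 53 genes named in the text, which are neither unselected nor unrelated. Of 228 groups of values tested, 59 gave such a library, where about 11 would by chance for unselected and unrelated values.

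Most of these values came from 3 libraries that also form the 3-library set, 13 kPa aligned number 3, 13 kPa isotropic number 3 and 90 kPa aligned number 4, given here in that order as CPM, each far above the other libraries of its group. ACTA2 was at 2991, 3414 and 3302 CPM, DES at 40.5, 48.3 and 49.0 CPM, CNN1 at 165, 183 and 179 CPM, LMOD1 at 122, 115 and 117 CPM, and TAGLN at 3778, 3965 and 3871 CPM. OXTR was at 271, 267 and 269 CPM, COL11A1 at 66.1, 58.5 and 68.0 CPM, and FMOD at 27.5, 32.4 and 22.8 CPM. CXCL2 was at 17.7, 6.61 and 15.3 CPM, CXCL6 at 56.25, 39.3 and 46.6 CPM, CXCL8 at 355, 179.5 and 337 CPM, BAMBI at 27.7, 28.35 and 29.0 CPM, and IER3 at 314, 259.7 and 313 CPM. TGFB1 was far below the rest of its groups there, at 115, 112 and 100.5 CPM. In 13 kPa aligned number 3 alone, PTGS2 stood apart at 93.1 CPM, ELN at 6.30 CPM and NR4A3 at 14.6 CPM. RPL5 stood apart at 847.5 CPM in 13 kPa isotropic number 3 and at 828 CPM in 90 kPa aligned number 4. PGR, at 9.53 CPM, and TNC, at 438 CPM, stood apart in 13 kPa isotropic number 3.

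The pattern in which libraries fall into 4 sets that cross the groups was weighed against depth, a few abundant genes and exchanged labels. After all libraries were thinned to 17.01 M counts, 0 libraries left their set, and without the 29 highest genes 0 left it, which argues against sequencing depth and a few abundant genes as the cause. Labels exchanged between groups would give set sizes within 1 library of 4, 8 or 12 among numbers 1 to 4. The sizes were 7, 6 and 3, with only that of 6 further away and the bound set when they were known, so they cannot decide. Numbers 5 to 8 hold every group, however labels are exchanged among them, and all lay in the 16-library set. Mean log2 CPM of the cell cycle list ran from 4.924 to 5.301 there, against 5.846 to 6.053, 3.48 to 3.739 and 2.367 to 2.524 in the sets of 7, 6 and 3. This argues against exchanged labels as the cause of differences that large, unless the groups differed only among numbers 1 to 4. With 5 sets, however, numbers 5 to 8 parted into sets of 8 and 8, a size that exchanged labels can give. Smaller differences from exchanged labels thus stay open. The sides of each main comparison also held unequal shares of these sets of 8. Values with the set term or within the 16-library set can therefore keep differences between them. A difference in sequencing run, cell lot, passage or culture between tissues may underlie the sets and stays open, since the labels give none of these for a library. No biological explanation was tested, because the design names none that crosses the groups.

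The pattern of lower matrix and contractile lists and a higher cell cycle list in 90 kPa isotropic than in 13 kPa aligned tissues was weighed against unequal shares of the sets and correlation between genes. With set means removed, the largest share of a list's mean difference that was left was 30.6%, for collagens (-0.22 to -0.07), followed by 19.7% for matrix glycoproteins (-0.26 to -0.05), 11.3% for the cell cycle (0.48 to 0.05) and 7.12% for contractile genes (-0.23 to -0.02). For the contractile and cell cycle lists the pattern may come from the sets, since camera with the set term no longer called them (adjusted p = 0.388 and 0.0765). This holds for the combined comparison. For average stiffness, camera with the set term still called the cell cycle list (adjusted p = 0.000418, but 0.882 with an estimated correlation). Correlation between genes bears on whether lists are called, not on their mean differences. With an estimated correlation the smallest adjusted p of camera without the set term was 0.537, so correlation may account for the calls. That estimate itself includes differences between the sets. For collagens and matrix glycoproteins it stays open whether set shares are the whole cause, since camera with the set term still called them (adjusted p = 0.00179 and 0.00887; adjusted p = 0.533 for both with an estimated correlation). An effect of the substrate on which state a tissue enters stays open and was not tested, with 1, 1, 1 and 0 libraries of the 3-library set in the 4 groups.

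The pattern of lower immediate early genes on isotropic than on aligned substrates was weighed against set shares, a single set and chance within sets. With set means removed the mean difference was -0.0897, against -0.104 from all libraries. Without the 3-library set it was -0.0558 (permutation p = 0.0704) against -0.0684. Most of the difference was left in both cases. Without the 3-library set, however, neither value was told apart from no difference (permutation p = 0.0704 with set means removed and 0.203 without). The test therefore cannot decide, and unequal set shares stay open. Within the 16-library set it was -0.0145, with -0.139 and -0.0728 in the 7-library and 6-library sets and -0.453 for the 1 isotropic library of the 3-library set, all below 0 but the first too small to tell apart from no difference, so a single part of the libraries may carry it. The permutation p within sets was 0.016 and, adjusted over 33 lists, 0.109, so chance order of libraries stays open, and with it an effect of alignment on these genes.

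Other splits of the same libraries were drawn 100 times per comparison, the real split included. For genes called by edgeR the real count was 0 in all 8 comparisons, so 100 of 100 splits gave at least as many by construction, and this says nothing about chance. The highest count of another split was 0 for the combined comparison, 923 for average stiffness, 3161 for average pattern, 1515 for stiffness in aligned, 0 for stiffness in isotropic, 2229 for pattern at 13 kPa, 0 for pattern at 90 kPa and 2481 for the interaction, and splits with so many calls point to a structure of the samples. For gene lists, 19 of 100 splits gave at least the 9 of the combined comparison (highest other 14). At least the 4 of average stiffness came in 76 (highest other 17) and the 11 of average pattern in 23 (highest other 15), so chance cannot be excluded. Other splits called at least 1 list in 99, 99 and 97 cases, with medians of 6, 6 and 7 lists. A call by camera at the preset correlation is thus common under shuffled labels. For the 1 gene called at 13 kPa with the set term, 2 of 100 splits within the sets gave as many (highest other 1), but only this comparison of the 8 was tried, because it had given a call, and the share is not corrected for that choice.

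Total counts stood apart in 13 kPa aligned number 8, at 26.6 M, and in 90 kPa aligned number 8, at 35.2 M. PTGES had 0 CPM in 13 kPa aligned number 4 and ASPN 0 CPM in 90 kPa aligned number 1, where 0 counts allow up to 0.144 and 0.151 CPM. SMAD7 was at 27.8 CPM in 13 kPa aligned number 5, FDFT1 at 142 CPM in 13 kPa aligned number 4, NRARP at 0.0971 CPM in 90 kPa aligned number 3, H4C14 at 0.563 CPM in 90 kPa isotropic number 5, H2BC4 at 0.0485 CPM in 90 kPa isotropic number 2 and CXCL3 at 0.0462 CPM in 90 kPa isotropic number 4. The NRARP, H2BC4 and CXCL3 values lay under the 0.158, 0.142 and 0.151 CPM that 0 counts allow in those libraries.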

How the results depend on the processing

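The set terms, surrogate variables, fits on parts of the libraries and permutations within sets were chosen only after the result was seen, and the other alternatives before the data were examined. No gene was called in any of the 8 comparisons by edgeR with DESeq2 size factors, no filter, the stricter filter, no robust estimation, a fit on the compared groups (not run for the averages and the interaction, which need all groups), the fit without the 3-library set, without the deepest library or on the 16-library set, or by the DESeq2 Wald test. The paired fit, with a replicate block by library number, called 0 genes in every comparison (329, 213 and 306 unadjusted in the combined, stiffness and pattern comparisons), but same-number libraries had correlations from -0.48 to 0.75 (median 0.34, 37 of 48 over 0.1, against a median of -0.13 for other pairs), and 8 of 32 libraries correlated best with their own number. Same-numbered libraries always lie in the same range of numbers, 1 to 4 or 5 to 8, while other pairs also mix these ranges. Numbers 5 to 8 of every group form the 16-library set, so the higher median does not show a pairing by number, and the labels give none. The set term, the finer set term and the surrogate variables each called 1 gene, SIK1, and limma voom 2 genes, in the pattern at 13 kPa, with 0 elsewhere, and SIK1 kept its direction under each of the 9 other settings it was run with. Its adjusted p was 0.0113, 0.00573, 0.0131 and 0.0199 there and 1 with the other planned settings of edgeR and DESeq2. Within the 7-library set the counts were 5 (combined), 2 (average stiffness), 11 (average pattern), 1 (stiffness in aligned), 4 (stiffness in isotropic), 7 (pattern at 13 kPa), 7 (pattern at 90 kPa) and 4 (interaction), and within the 6-library set 10, 10, 11, 7, 11, 13, 9 and 15 in the same order. The genes in the 7-library counts of 5 or fewer, named after their values were seen, were NME1-NME2, EGR1, CCN1, KIAA0408 and WDR5B-DT (combined), NME1-NME2 and KIAA0408 (average stiffness), KIAA0408 (stiffness in aligned), NPIPA7, STIMATE-MUSTN1, ENSG00000258377 and ENSG00000267520 (stiffness in isotropic) and KIAA0408, NPIPA7, ENSG00000267520 and F8A2 (interaction). These fits have 1 to 2 libraries per group, whose lone libraries are assumed to vary like the others, and the cause was not tested. Lists called with the preset correlation numbered 9, 4 and 11 in the combined, stiffness and pattern comparisons. With the stricter filter the counts were 15, 7 and 15, where fewer genes form the background. With the set term at the preset correlation they were 7, 3 and 8. With the estimated correlation they were 0, 0 and 0, and with the set term and the estimated correlation also 0, 0 and 0.

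Of the log2 fold changes of named genes, those that turned were all uncalled, and the cause was not tested unless a set term is named, which removes the differences between sets by construction. With the set term, in the combined comparison, DES was at 0.113, PTGES at 0.0828, OXTR at 0.104, GJA1 at 0.012, COL11A1 at 0.0451 and TGFB1 at -0.0933. For average stiffness OXTR was at 0.0437 and TGFB1 at -0.0429, and for average pattern DES at 0.156, CNN1 at 0.0156, OXTR at 0.060, GJA1 at 0.0303 and PGR at -0.0215. With surrogate variables, in the combined comparison, DES was at 0.114, PTGES at 0.165, OXTR at 0.104, GJA1 at 0.0238, COL11A1 at 0.0154 and TGFB1 at -0.0665. For average stiffness ACTA2 was at 0.0402, OXTR at 0.0585, FMOD at 0.00152 and TGFB1 at -0.0541, and for average pattern DES at 0.118, OXTR at 0.0459, GJA1 at 0.0357 and PGR at -0.0242. With limma voom, in the combined comparison, DES was at 0.0307, OXTR at 0.152, GJA1 at 0.0053, COL11A1 at 0.175, TGFB1 at -0.0561, NR4A3 at 0.351 and ESR1 at -0.00941. For average stiffness OXTR was at 0.101, ELN at 0.409, TGFB1 at -0.0678 and ESR1 at 0.00967. For average pattern DES was at 0.179, OXTR at 0.0504, GJA1 at 0.055, COL11A1 at 0.0156, NR4A3 at 0.256, MX1 at -0.0689, TGFB1 at 0.0117 and ESR1 at -0.0191. With the DESeq2 Wald test DES was at 0.0498 and COL11A1 at 0.0489 in the combined comparison, and DES at 0.147, CNN1 at 0.00915 and NR4A3 at 0.0808 in the average pattern. The default settings of that test can replace outlying counts, and whether this turned these estimates was not tested. TGFB1 was at -0.00177 in the combined comparison with the stricter filter, and with the replicate block PGR was at 0.0083 there and TGFB1 at 0.000325 in the average pattern. Size factors, no filter and no robust estimation turned none of the 92 estimates. The stricter filter left out 28 of them. Depth limits genes with few counts, such as ELN, NR4A3, CXCL2 and H4C14.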

Other observations

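Every value below with a set term or with permutations within sets comes from tests chosen only after the sets were seen. The immediate early list did not pass within the sets for the average pattern (mean log2 difference -0.09, adjusted permutation p = 0.109, -0.0558 without the 3-library set and -0.01 in the 16-library set). With the set term, 6 of 23 immediate early genes passed in the average pattern comparison when adjusted over the list alone, and 0 over all genes (adjusted p = 0.857 for each). On the isotropic pattern KLF2, a gene known to respond to mechanical flow in vessels, was at -0.20 ± 0.0494 (log2, SE), JUN at -0.11 ± 0.0355, EGR2 at -0.31 ± 0.106, IER2 at -0.11 ± 0.0409 and DUSP6 at -0.07 ± 0.0272, while BTG2, which restrains growth, was at 0.20 ± 0.0619. Without the set term they were at -0.17 ± 0.165, -0.08 ± 0.143, -0.30 ± 0.425, -0.06 ± 0.104, 0.02 ± 0.187 and 0.11 ± 0.135 in the same order. These genes were chosen after their values were seen. Under the same rule 2 of 24 cholesterol synthesis genes, 2 of 7 decidual markers, 1 of 20 p53 targets and 1 of 16 contraction-associated genes passed for the pattern, the last of them PTGFR at 0.19 ± 0.0605, and 1 of 19 ion channel genes and 1 of 8 histone genes for stiffness. Within the 7-library set alone, EGR1 was at -0.84 ± 0.0697 (edgeR adjusted p = 1.57e-07) and CCN1 at -0.34 ± 0.0490 (adjusted p = 0.00023) on isotropic against aligned gels, with 4 and 3 libraries and both named after their values were seen, while in the 16-library set the EGR1 difference was 0.05 and the CCN1 difference 0.00.

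Other gene groups also had differences within sets that did not pass after adjustment over 33 lists. For the average pattern, 5 of the 33 had an unadjusted permutation p under 0.05 within the sets, and 1 in the 16-library set alone. Not all of these are named. Decidual stroma markers were lower on the isotropic pattern by a mean log2 difference of -0.13 (permutation p = 0.00325, adjusted p = 0.107) and Notch genes by -0.13 (permutation p = 0.00858, adjusted p = 0.109), and the Notch difference was -0.13, -0.19 and -0.15 within the sets of 16, 7 and 6 libraries. Replication-dependent histone genes differed by 0.19 between 90 and 13 kPa (permutation p = 0.00605, adjusted p = 0.200), with 0.07, 0.40 and 0.31 in the same sets. The Notch and histone lists rest on genes of low expression, with medians of 1.15 and 1.27 log2 CPM over their tested members. Of the 26 histone genes listed, 8 were tested.

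Other genes also had different levels in the sets. IL6, an inflammatory cytokine, had a median of 477 CPM in the 3-library set, 106.5 CPM in the 6-library set, 24.4 CPM in the 16-library set and 16.5 CPM in the 7-library set, and CDKN1A, which stops the cell cycle, 1341, 871, 770 and 466 CPM. TOP2A, a gene of dividing cells, ran the other way, with 18.2, 43.0, 122 and 229 CPM. Libraries numbered 5 to 8 detected 20081 to 21467 genes, and those numbered 1 to 4 18797 to 20008, with no overlap. These 3 genes were named after their values were seen, and differences between sets were not tested, since the sets were drawn from the same data.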
